A study of Mus musculus with 96 samples.

How the data were processed

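Per the labels, the animals were C57Bl/6 mice that were irradiated or left untreated and fed chow or a high fat diet. Satellite cells, the stem cells of skeletal muscle, were profiled by RNA sequencing, by capture of methylated DNA with a methyl-binding domain (MBD) followed by sequencing, and by reduced representation bisulfite sequencing (RRBS), which reads methylation of single cytosines in MspI fragments. The stromal vascular fraction, the mixed non-adipocyte cells of fat tissue, was profiled by RRBS. The 96 samples formed 16 groups of a cell type, an assay, a radiation state and a diet. Each group held 6 samples, except in the RRBS of the stromal vascular fraction, with 6 control chow, 7 control high fat diet, 4 irradiated chow and 7 irradiated high fat diet samples. The labels do not say which samples came from the same animal, and the sex, the radiation dose and the interval between irradiation and collection are not given in the sources used here.

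Per the labels' protocols, RNA libraries were stranded total RNA libraries depleted of ribosomal RNA, MBD libraries were made from sonicated DNA captured on MethylMiner beads, and RRBS libraries were made without gel selection from MspI digests. Per the submitters' processing notes, the genome build was mm10. The submitters name Trim Galore 0.4.0, TopHat2, featureCounts and edgeR for RNA, Trimmomatic, Bowtie2, Picard, featureCounts and edgeR for MBD, and Trim Galore 0.4.0, cutadapt 1.8.3, Bismark 0.14.4 and Bowtie2 2.2.6 for RRBS, with CASAVA 1.8.2 for all 3 assays. Versions of the tools printed without one, the settings and the order of steps are not given in the sources used here.

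All 14 tables held the authors' own comparison statistics, and 0 columns held values of single samples. The RNA and MBD tables gave, per the file headers, a log2 fold change, a mean abundance as log2 CPM, a likelihood ratio and a p-value for each gene or region, and the RNA tables also gave an adjusted p. In the MBD tables the authors had written notes and tallies under the listed regions in some of the same columns, so those deposited columns were treated as a score with no fixed range, and lines without a chromosome were left out. The RRBS tables gave, per the file headers, a median p-value and a median difference in methylation between 2 groups, given here in percentage points as group 1 minus group 2. Columns with the levels of the groups were not used, because the groups are not named. Because no counts, coverage or library totals were used, the depth behind each value is unknown, no interval that needs depth was computed, and no standard deviation between animals can be given. The RNA and MBD p-values measure the spread between the samples the authors fitted. For RRBS, what spread the median p-value measures is not given in the sources used here. It reached 9.88e-324 for a region at the start of Med16 in the stromal vascular fraction. RRBS p-values are therefore not read here as a measure of the spread between animals.

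What a contrast stood for was settled from the values where possible. Multiplying each adjusted p by its rank and dividing by its p-value gave 12371 tested genes in each of the 4 RNA tables, and each table listed every gene with an adjusted p under 0.1. For the 13 genes in all 3 irradiation tables, the fold change over both diets equalled the chow effect plus the high fat diet effect, with a largest deviation of 3.11e-15. Values over both diets are therefore given here as the deposited number divided by 2, which is the mean of the effects on the 2 diets, and the effect on the high fat diet was obtained for a chow gene by subtraction. For the MBD tables, neither the headers nor the labels name the 2 sides of the contrast, and for the RRBS tables they do not say which samples are group 1 and which are group 2. Directions in these tables are given as coded, with no treatment attached.

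The design was written before the data were examined. With comparison tables only, no refit was possible, and the result of each comparison was the number of genes or regions listed on each side with a two-sided exact binomial test of the split, which describes the list because genes are not independent replicates. RNA genes counted at an adjusted p under 0.05. The design expected adjusted p-values for MBD and RRBS as well. Only unadjusted p-values were given, so all regions the authors listed were used. Two-sided Fisher exact tests compared directions between lists and between assays, with Benjamini-Hochberg adjustment over the 23 gene lists fixed beforehand. Membership was matched by symbol and, through Ensembl identifiers, by current symbol, for which all genes of the RNA tables had a match. A test of whether a list held more genes than its size and the 12371 tested genes would give was added after the data were seen. It counted every list member as tested, which taken alone makes it conservative. It also treated genes as independent draws, which genes of a list need not be, and this can make its p-values too small. For RRBS, a list member counted when a region within 2 kb of its start differed by 10 points or more. An approximate standard error of a fold change was taken as its size divided by the square root of its likelihood ratio, and the difference between the diets was set against that of the summed effect. Rank correlations across genes or regions were tested with 100000 permutations. The computations used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.

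The steps were tested on simulated data. With random directions for the 827 genes listed over both diets, 0% of 100 simulations called any list, and a planted list of 20 genes with 18 higher was called in 100% of them. Directions were drawn independently for each gene, which genes of a list need not follow. No fixed list had more than 8 members among the 827 genes, so the 100% does not apply to these lists. For the difference between diets, simulated on 5000 genes, 4.54% of unchanged genes had an unadjusted p under 0.05, and 75.5% of 200 genes with a difference of 4 standard errors were called at an adjusted p under 0.05.

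Named RNA genes were the 10 highest and 10 lowest fold changes at an adjusted p under 0.05 among genes at or above the median abundance of the table, every gene of a table listing 20 or fewer, and up to 4 members per list with the smallest adjusted p. Named regions were the 5 highest and 5 lowest values per MBD table and the 5 largest differences on each side per RRBS table, of which the leading ones are printed. Members of the fixed lists named for MBD and RRBS, and the marker genes whose abundance is given, were chosen after their values were seen. Genes with both an RNA and an MBD promoter entry were named where there were 20 or fewer. Alternatives tried were stricter and looser thresholds, a minimum fold change or difference, abundant genes only, autosomes only, 1 region per gene, clustered regions and other distances. A second normalization, a replicate block, leaving out replicates and coverage minimums need per-sample values and were not run.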

Results

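The study crossed irradiation with diet in mice and measured gene expression and DNA methylation in muscle satellite cells, and DNA methylation in the stromal vascular fraction of fat. From its title, it addressed how ionizing radiation and a high fat diet together alter muscle and fat progenitor cells. RNA, MBD and RRBS profiles of satellite cells came from 24 libraries each, with 6 per group, and RRBS profiles of the stromal vascular fraction came from 24 libraries in groups of 4 to 7. All values below are the authors' comparison statistics or were computed from them, and coordinates refer to mm10. Depth per library is unknown.

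The first comparison asked what irradiation changed in satellite cells of chow-fed mice. In the authors' deposited table for chow, the lowest log2 fold changes among abundant genes belonged to Fgf21, a secreted metabolic hormone, at -2.84 (adjusted p = 0.000313), and to Grb10, an imprinted adaptor that restrains insulin receptor signalling, at -2.10 (adjusted p = 0.000708). The same deposited table listed the stress-responsive muscle protein Ankrd2 at -1.59, the muscle creatine kinase Ckm at -1.50, the collagen chain Col1a2 at -1.50, the dipeptidase Dpep1 at -1.46, the ubiquitin ligase Hecw2 at -1.24 and the dehydrogenase family member Dhrs7c at -1.02. Enzymes of mitochondrial folate and of serine synthesis fell as well, with Aldh1l2 at -1.01 and Psat1 also lower (adjusted p = 0.00117) in the authors' deposited table. On the higher side, that deposited table was led among abundant genes by the integrin subunit Itga4 at 1.35, the imprinted zinc finger gene Plagl1 at 1.22 and the chemokine Cx3cl1 at 1.07, followed by the RNA-binding protein Igf2bp3 at 0.89 (adjusted p = 0.000703), the cell cycle kinase Cdk6 at 0.77, the semaphorin receptor Plxnb1 at 0.74, Specc1 at 0.73, the chromatin protein Hmgb3 at 0.72, and Sh3pxd2b and Abhd2 at 0.65 each. Fgf21 lies on chromosome 7 from 45613907 to 45615490 and Grb10 on chromosome 11 from 11930508 to 12037401.

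Counted over all 12371 tested genes, 155 were listed at an adjusted p under 0.05 in the authors' deposited table for chow, 48 higher and 107 lower after irradiation (exact binomial p = 2.44e-06). Among the gene lists, 4 members of the insulin and glucose list fell and 0 rose. They were Grb10, the kinase Akt2 at -0.58, the glycogen synthase Gys1 at -0.54 and the glycolytic enzyme Pfkp at -0.49 in the authors' deposited table. All 4 also passed when adjusted over the list alone, which their passing over all tested genes had fixed in advance. With 0.464 members expected among the 155 genes, the adjusted p for this number was 0.0261, in a test added after the data were seen, while the planned test of direction gave an adjusted p of 1. With only 4 members, all lower, the test of direction could hardly pass (unadjusted Fisher exact p = 0.312). Markers of other cell types were also among the genes that fell. The endothelial markers Cdh5 and Pecam1 stood at -3.03 (adjusted p = 0.0158) and -2.25 (adjusted p = 0.0498), the fibroblast and surface marker Thy1 at -2.20 (adjusted p = 0.000313) and the perivascular marker Mcam at -0.79 (adjusted p = 0.0441) in the authors' deposited table. Cdh5, Pecam1 and Thy1 were scarce transcripts, with mean abundances of 0.33, 0.60 and 0.68 on the log2 CPM scale. In the list of extracellular matrix genes, Fbln5 stood at -1.33 and the collagen crosslinking enzyme Loxl2 at -1.19, and in the stress list the haem oxygenase Hmox1 stood at -0.81 in the authors' deposited table. For the imprinted list, Plagl1 and Dlk1 rose and Grb10 fell, with Dlk1 at 1.91.

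A second comparison asked the same of mice on the high fat diet. In the authors' deposited table for this diet, 8 genes were listed at an adjusted p under 0.05, 6 higher and 2 lower (exact binomial p = 0.289). The 6 that rose were Dcx, a microtubule protein of migrating neurons, at a log2 fold change of 2.48, the neurofilament genes Nefl at 2.42 and Nefm at 1.77, the calpain family member Capn6 at 2.58, the transcription factor Tbx20 at 2.16 and the fast myosin heavy chain gene Myh2 at 4.71, all from the authors' deposited table. Those that fell were the sphingosine phosphate receptor S1pr1 at -1.64 and the transcript 5930412G12Rik at -2.66 in the same deposited table. A further 10 genes had adjusted p-values between 0.05 and 0.1, among them Grb10 at -1.66 (adjusted p = 0.0617), C1ql3 at 3.02, Pclo at 1.33, Nrk at 1.35, Synpr at 1.42, Hecw2 at -1.16, Cadps at 2.42, Dpep1 at -1.21 and Dlk1 at 1.82 in the authors' deposited table.

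Between the 2 diets, irradiation moved overlapping genes. At an adjusted p under 0.05, 5 genes were in both deposited lists, against 0.1 expected from independent lists of 155 and 8 genes (exact hypergeometric p = 1.57e-08), and they were 3 higher and 2 lower on both diets. Dcx, Capn6, Tbx20, S1pr1 and 5930412G12Rik made up this set. With 5 genes split 3 to 2 the Fisher exact test of direction cannot fall below 0.1, its observed value. At the authors' threshold of 0.1 the lists of 322 and 18 genes shared 13, all in the same direction (Fisher exact p = 0.000583). The 2 comparisons share no libraries. The effect on the high fat diet could be recovered for 309 of the 322 chow genes, those also listed for the sum of both diets, a condition that favours effects of the same sign. It had the same sign in all 309 and was smaller than on chow for 296 of them, with a median ratio of 0.598 and quartiles of 0.446 and 0.761. For the other 13, absence from the list of the sum gave only an approximate bound, which was of opposite sign for 2 of them. Cdh5, at -3.03 on chow in the authors' deposited table, had a bound of at least 0.41 on the high fat diet, and Epb4.1l4a, higher on chow in that deposited table (adjusted p = 0.0431), had a bound of at most -0.010. Both were named after their values were seen. Selection on chow inflates the chow value, so the ratio is not an estimate of the true attenuation. Tested as an approximate difference between the diets, 15 of 314 genes had an unadjusted p under 0.05 and 0 passed the adjustment, with a smallest adjusted p of 0.594. The 13 genes with only a bound were not in this test, and their differences were at least 1.88 to 3.23 approximate standard errors, so a different response of these genes stays open.

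**Figure D1:**
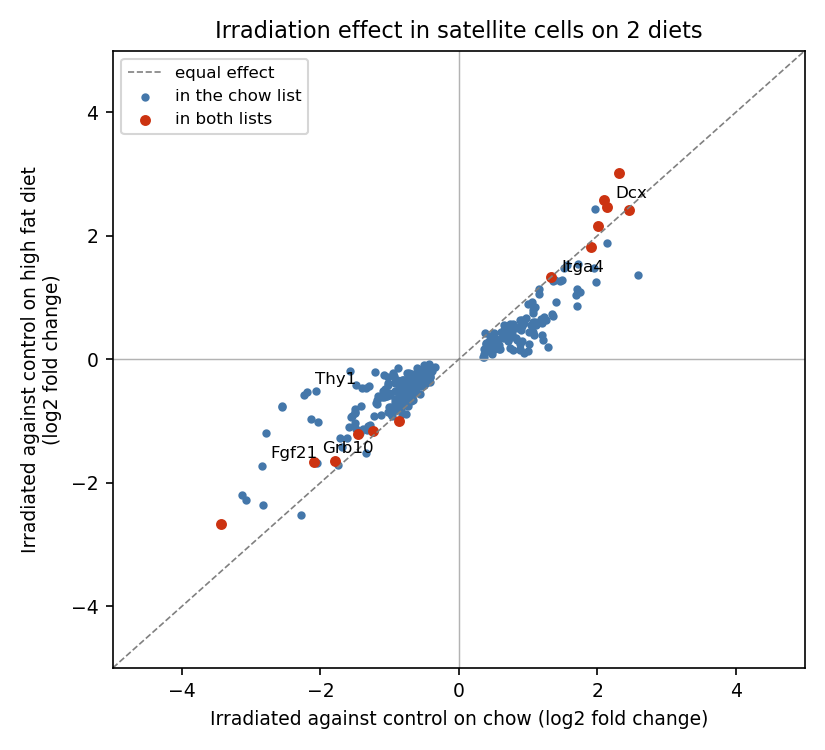
Log2 fold change after irradiation in satellite cells on the high fat diet (vertical) against that on chow (horizontal) for the 309 genes of the chow list whose effect on the high fat diet could be recovered. The 13 genes in both lists are in red, the dashed line marks equal effects, and 296 points are closer to 0 on the high fat diet. The 13 chow genes not listed for the sum of both diets, 2 of them with a bound of opposite sign, are not drawn, and the condition favours points in the lower left and upper right quadrants.

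In irradiated mice, the effect of diet itself was listed for 1 gene. The lysyl oxidase family gene Loxl2, on chromosome 14 from 69609478 to 69693698, was higher on the high fat diet than on chow by a log2 fold change of 1.68 (adjusted p = 0.0195) in the authors' deposited table. A table for diet in unirradiated mice was not analysed here.

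Over both diets, 827 genes were listed at an adjusted p under 0.05, 377 higher and 450 lower after irradiation (exact binomial p = 0.0122). At the authors' threshold of 0.1 the list grew to 823 higher and 872 lower, a split that no longer departed from even (p = 0.244). Mean log2 fold changes, computed by dividing the value in the authors' deposited table by 2, were highest among abundant genes for Myh2 at 3.79, the carbonic anhydrase Car3 at 1.43, the sarcomere protein Myot at 1.38, the extracellular matrix protein Frem2 at 1.33, Itga4 at 1.31, Nav3 at 0.99, Plagl1 at 0.96, Rgs5 at 0.94, Cx3cl1 at 0.84 and the kinase Prkcb at 0.83. They were lowest for Fgf21 at -2.29 (adjusted p = 7.87e-07), Grb10 at -1.88 (adjusted p = 5.03e-07), the imprinted cyclin-dependent kinase inhibitor Cdkn1c at -1.42, Ankrd2 at -1.34, Dpep1 at -1.34, Hecw2 at -1.20, Col1a2 at -1.18, Ckm at -1.16, the myoblast fusion gene Mymx, listed as Gm7325, at -0.94, and the methionine adenosyltransferase Mat2a at -0.94.

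Muscle genes were among those that fell, although no muscle list passed the test of direction. Of 27 genes in the satellite cell and myoblast list, 6 fell and 0 rose over both diets. All 6 passed when adjusted over the list alone, which their passing over all tested genes had fixed in advance. Besides Mymx, they were its partner in myoblast fusion Mymk, listed as Tmem8c, at -0.67, the muscle cadherin Cdh15 at -0.46, the differentiation factor Myog at -0.58, the acetylcholine receptor subunit Chrna1 at -0.40 and Ncam1 at -0.41, each from the authors' deposited table divided by 2. Neither the direction (Fisher exact p = 0.0343, adjusted p = 0.79) nor the number (exact hypergeometric p = 0.00771, adjusted p = 0.0887) held after adjustment over the 23 lists. In the muscle contraction list 4 fell, including Ckm, the cardiac actin Actc1 at -0.60 and Tpm2 at -0.54, and 1 rose, Myh2. Markers of other cells moved beside them. The fibroblast list had 4 lower, Thy1 at -1.37, Col1a2, Col15a1 at -1.37 and Dcn at -1.29, and 0 higher. Macrophage genes Mrc1 and Itgam stood at -0.59 and -0.79, and of the perivascular genes Acta2 fell to -0.93 and Mcam to -0.56 while Rgs5 rose. No endothelial gene was listed over both diets, and the adipocyte list had Scd1 at -0.46.

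Genes of insulin and glucose handling were 3 higher and 5 lower (8 against 2.47 expected, adjusted p = 0.0602), with Akt2 at -0.50, Gys1 at -0.39 and the transcription factor Foxo1 at 0.41. Imprinted genes were 4 higher and 2 lower, with Dlk1 at 1.86 and Plagl1 on the higher side and Grb10 and Cdkn1c on the lower. The Wnt and Notch list had 3 higher, Lef1 at 0.94 (adjusted p = 0.00107), Axin2 at 1.05 and Sfrp1 at 0.85, and 0 lower. Among stress genes Ddit3 at -1.33, Atf4 at -0.41 and Hmox1 at -0.57 fell and Dusp1 at 0.35 rose. The p53 list, whose genes respond to DNA damage, had Gadd45a at -0.47 and Gdf15 at -0.90 and 0 higher. Smaller counts were found for fatty acid oxidation, with Etfb at -0.40 and Etfa at -0.32, for interferon response with Ifi27 at -0.38, for secreted factors with Igfbp5 at 0.64, for extracellular matrix with Lama2 at 0.45, Tgfbr2 at 0.32 and Fbln5 at -1.24, and for the DNA methylation machinery with Tet3 at 0.32, Zbtb38 at 0.25 and Gadd45b at -0.43. Hox, ribosomal protein, histone and endothelial lists had 0 members at this threshold. No list passed the test of direction after adjustment, where the smallest adjusted p was 0.79. That value came from 6 lower and 0 higher. With at most 8 listed members per list, the test could hardly find a direction. Values of single genes here are those in the authors' deposited table divided by 2.

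At the looser threshold of 0.1, chosen after the data were seen, the cell cycle list had 9 members higher and 0 lower (Fisher exact p = 0.00147, adjusted p = 0.0337), of which Cenpf at 0.59 and Mki67 at 0.61 also passed 0.05, and at least 4 of the 9 passed when adjusted over the list alone. At 0.05 this list had 2 higher and 0 lower (Fisher exact adjusted p = 0.955). The DNA repair list had 8 higher and 1 lower (adjusted p = 0.181), led by Mdc1 at 0.56 and Brca2 at 0.51. Lists on the lower side had the same Fisher exact adjusted p. The satellite cell and myoblast list and the muscle contraction list each had 1 higher and 8 lower. The ribosomal protein list had 0 higher and 6 lower. Oxidative phosphorylation genes were 15 in number against 5.07 expected (adjusted p = 0.00117, in the test added later), and among them the 5 encoded in mitochondria were higher by 0.34 to 0.44 and the 10 encoded in the nucleus, such as Ndufa9 at -0.38 and Cox6a2 at -0.82, were lower, a division noticed after the values were seen. At 0.05 this list had 0 higher and 2 lower against 2.47 expected (adjusted p = 1). These values of single genes are from the authors' deposited table, divided by 2.

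**Figure D2:**
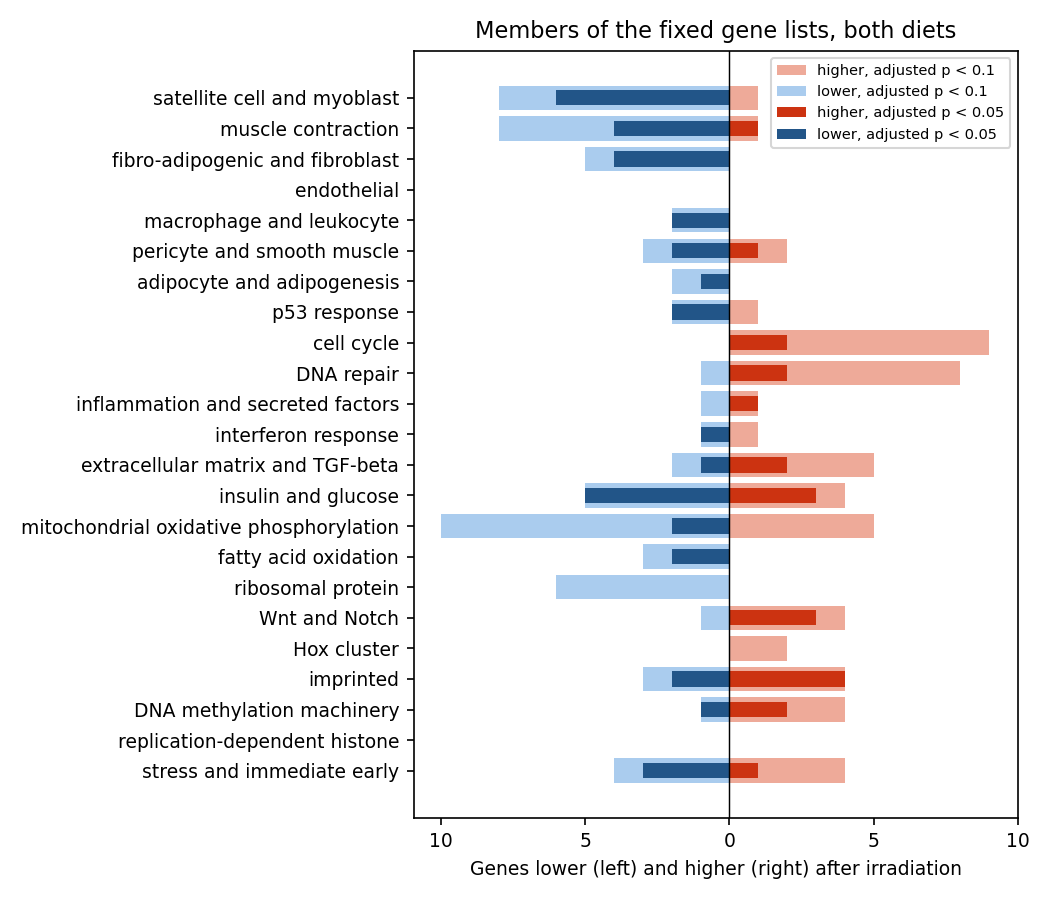
Number of genes lower (blue, left) and higher (red, right) after irradiation over both diets for each of the 23 gene lists, at an adjusted p under 0.05 (dark, narrow bars) and under 0.1 (light, wide bars). The cell cycle list reaches 9 genes on the higher side and 0 on the lower at 0.1, and the satellite cell and myoblast list has 6 on the lower side and 0 on the higher at 0.05.

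MBD capture, which reads the amount of methylated DNA over a region, was listed by the authors for promoters, CpG islands, CpG shores and gene exons of satellite cells, with an unadjusted p and without naming the 2 sides. The highest promoter values in the authors' deposited table were Vsig1 on chromosome X from 140906608 to 140908607 with a log2 fold change of 2.96, Tmem161b at 2.60 and the defensin gene Defb39 at 2.22, and the lowest were Ddx3y at -2.10, Rabgef1 at -2.01, the proton pump subunit Tcirg1 at -1.39, Acsm3 at -1.15 and the homeobox gene Hoxc8 at -1.13. Among CpG islands the authors' deposited table was headed by Pparg, the master regulator of adipocyte differentiation, whose promoter island on chromosome 6 from 115360968 to 115362226 stood at 2.49 (unadjusted p = 6.32e-06), followed by Mdfi, an inhibitor of myogenic factors, at 2.07, Cldn11 at 2.04, Fcrlb at 2.02 and BC048602 at 1.99. The island of Cebpa, another adipogenic factor, stood at 1.75. Pparg and Mdfi, at mean abundances of 5.79 and 5.85 log2 CPM, lay below the island median of 6.40. Below that median 100% of the listed islands were higher, so the direction of Pparg and Mdfi is not particular to them. Lowest were Yy2 at -0.64, Tns1 at -0.62, Cdk9 at -0.56, Golga4 at -0.55 and an intergenic island nearest Zfhx3 at -0.53. Shores were led by Bahd1 at 2.45 and Vipr1 at 2.43, with Rnh1 at -2.77 and Gadd45gip1 at -2.04 at the other end. In exons the extremes were short regions, with Gm14393 at 2.19 and Mir5123 at -1.85 in the authors' deposited table.

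The classes differed in direction. Of 373 promoter regions 90 were higher and 283 lower (exact binomial p = 2.37e-24), of 84 islands 68 were higher and 16 lower (p = 8.54e-09), of 190 shores 65 were higher and 125 lower (p = 1.6e-05), and of 2455 exon regions 1624 were higher and 831 lower (p = 1.62e-58). The 373 promoter entries repeated some positions and covered 322 distinct intervals. With 1 region per gene symbol, 23.7% of 317 promoters were higher (exact binomial p = 1.2e-21). All 2455 exon regions were given on the plus strand. Genes of the minus strand, such as Cycs and Hoxa4, were among them, so this label does not show that part of the exons is missing. Genes listed for both a promoter and exons had the same direction in 49 of 51 cases (Fisher exact p = 1.55e-06), which is partly the same DNA where the regions overlap. Counting only absolute log2 fold changes of at least 1 turned the split for promoters to 75.2% higher and for shores to 90.9% higher. In a comparison made after the data were seen, direction followed abundance in all classes, as the plot of direction by abundance shows, with rank correlations of fold change and abundance from -0.342 to -0.894 (permutation p = 1e-05 for each, the smallest that 100000 permutations can give). No gene list differed in direction from the other listed genes after adjustment in any class, with a smallest adjusted p of 0.138. In promoters, islands and shores a list held at most 3 listed genes, too few for this test to decide.

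**Figure D3:**
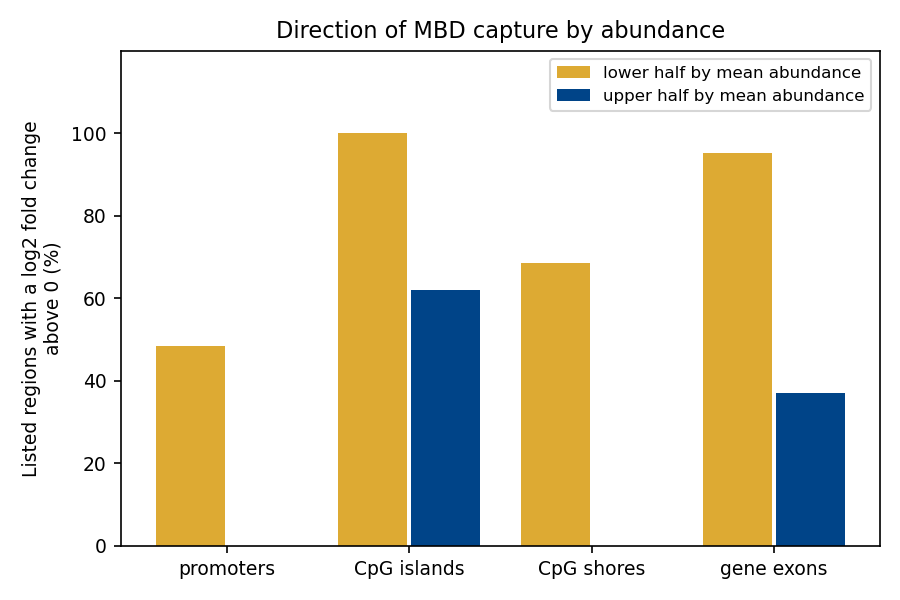
Percentage of the regions in each MBD table with a log2 fold change above 0, for regions below (yellow) and above (blue) the median of mean abundance. Promoters go from 48.4% to 0%, islands from 100% to 61.9%, shores from 68.4% to 0% and exons from 95.2% to 37.1%.

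RRBS in the stromal vascular fraction asked which CpGs differed with radiation, with diet and with their interaction. Differences in methylation are in percentage points, group 1 minus group 2, and the sources do not say which samples form either group. For radiation, the highest differences in the authors' deposited table were 63.4 points upstream of Mir6546 on chromosome 1 from 171065944 to 171065954, 59.7 points in an intron on chromosome X with Las1l as the nearest gene, and 45.4 points upstream of the long non-coding RNA Malat1. On the other side were the start of the Mediator subunit Med16 at -50.0 points, an intron nearest Cdc42bpa at -48.0 points, the promoter of the corepressor Ctbp1 at -45.7 points and the promoter of Wnt6 at -45.2 points. For diet, intergenic regions nearest Barhl1 and nearest Fgfr3 stood at 60.6 and 51.7 points, while a 3' UTR region nearest Trib1 stood at -53.2 points and an intron near Tbx18 at -51.8 points in the authors' deposited table. For the interaction, the extremes were an exon region nearest Marveld2 at 63.3 points and the promoter of the cadherin Celsr1 at -65.5 points in the authors' deposited table. At the promoter of the imprinted gene Grb10, on chromosome 11 from 12025820 to 12025882, the deposited radiation table gave -28.5 points. Within that stretch the diet difference was -25.0 points and the interaction 19.7 points, so the change there was not particular to radiation.

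In number, the deposited radiation table for this fraction held 5493 regions, 3334 higher in group 1 and 2159 higher in group 2 (exact binomial p = 6.2e-57). For diet there were 7997, split 3457 to 4540 (exact binomial p = 8.5e-34), and for the interaction 1207, split 389 to 818 (exact binomial p = 1.33e-35). Many differences were small. For radiation 58.6% of regions differed by less than 1 point and 1684 by at least 10 points, of which 1381 were higher in group 1 and 303 in group 2 (exact binomial p = 3.57e-164). For diet 4832 differed by at least 10 points, with a split that no longer departed from even (50.9% higher in group 1, exact binomial p = 0.211). The interaction had 497 such regions, 86 higher in group 1 and 411 in group 2 (exact binomial p = 7.91e-52). Regions lay close to genes, with 85.6% of the radiation regions within 1000 bp of a transcription start. Over all RRBS comparisons of both cell types this share ranged from 78.8% to 87.1%, so it is not particular to radiation. The share among all regions the assay read is not given in the sources used here.

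The same assay in satellite cells listed more regions for radiation. In the authors' deposited table for radiation, the promoter of the histocompatibility gene H2-K1 on chromosome 17 from 33999669 to 33999722 stood at 45.2 points, the promoter of Clic5 at 45.1 points, and an intron region nearest Camta1 at 44.5 points. In the other direction a 3' UTR region nearest Tkt stood at -51.6 points, the promoter of Plekhn1 at -47.1 points, and a region 2484 bp downstream of the start of the tumour suppressor gene Hic1 at -44.9 points. The promoters of H2-K1 and Clic5 were also among the highest differences in the deposited diet table, at 45.1 and 45.2 points, next to an exon region nearest Flcn at 49.0 points, with the start of the kinase gene Csk at -45.5 points and Mir203 at -42.3 points on the other side. The interaction extremes were an exon region nearest BC021891 at 67.4 points and a region downstream of the start of the actin-binding gene Coro1a at -67.1 points in the authors' deposited table.

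There were 9827 regions for radiation, 4724 higher in group 1 and 5103 higher in group 2 (exact binomial p = 0.000137), 9617 for diet, split 4994 to 4623 (p = 0.000161), and 1057 for the interaction, split 474 to 583 (p = 0.000886). At differences of at least 10 points 5101, 4606 and 347 were left, and the diet split was then 49.5% higher in group 1 (exact binomial p = 0.507), while radiation was 2346 to 2755 (p = 1.09e-08) and the interaction 37 to 310 (p = 7.72e-55). No gene list differed in direction from other genes after adjustment in any RRBS table of either cell type, with a smallest adjusted p of 0.409. That value came from 1 gene. Many lists had few or no genes with a region of at least 10 points near the start, too few for this test to decide. For the interaction nearly all other genes were higher in group 2, 331 against 6 in the stromal vascular fraction. A list on that side could not pass there. Of the p53 list, 6 genes had such a region near the start in the satellite cell radiation table, 3 higher in each group, including Mdm2 at -34.1 points and Cdkn2a at 33.6 points in the authors' deposited table. The satellite cell and myoblast list had 3 genes higher in group 1 and 1 higher in group 2 (Fisher exact p = 0.369, adjusted p = 1), among them the stem cell factor Pax7 at 34.0 points and Spry1 at -34.5 points in the authors' deposited table. Leading members of several other lists had radiation differences of similar size. Examples were Akt1 at -34.4 points and the ribosomal protein genes Rpl22 at -34.4 and Rpl13 at 34.0 points. A difference of this size is therefore not particular to Mdm2, Cdkn2a, Pax7 or Spry1.

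The cell types were compared at the same position and nearby. For radiation 186 regions were listed at the same position in both, with 98 on the same side (Fisher exact p = 0.461), and for diet 219 were, with 114 on the same side (p = 0.4), so no departure from chance was detected in either. Of the stromal vascular regions 1838 for radiation and 2360 for diet lay within 100 bp of a satellite cell region, with 51.3% and 49.4% on the same side (Fisher exact p = 0.113 and 0.831), and 2781 and 3585 lay within 1000 bp. Within 1 cell type the radiation and diet tables shared more, and whether they have samples in common is not given in the sources used here. In the stromal vascular fraction 2987 regions were in both and 63% had the same side (Fisher exact p = 5.19e-131), and in satellite cells 5003 were in both and 46.3% did (p = 7.14e-08). Simulated unchanged differences had the same sign in 66.6% of cases with shared samples on the same side of both comparisons and in 33.4% with shared samples on opposite sides. The simulation kept every difference, whereas the regions compared here had to be listed for both radiation and diet. For this reason, and because the layout is unknown, the simulated values cannot decide whether radiation and diet had a shared effect. The number of regions tested is not given in the sources used here.

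Across assays in satellite cells, 10 genes were listed at an adjusted p under 0.05 for irradiation over both diets and also in the MBD promoter table, and 4 of them had the same sign in both as coded and 6 the opposite (Fisher exact p = 1). These numbers trade places if the unnamed sides of the MBD contrast are turned. For MBD exons, compared after the data were seen, 67 genes were in both lists with 43.3% of the same sign (Fisher exact p = 0.205), and at an adjusted p under 0.1 there were 138 genes with 41.3% (Fisher exact p = 0.0222). Within 3 equal classes of capture abundance of these 138 genes the Fisher exact p was 0.183 or more. In the lowest class capture was lower for only 1 of 46 genes, and in the highest it was higher for only 4 of 46. These 2 classes could hardly decide. In the middle class capture was higher for 20 and lower for 4 genes that rose, against 14 and 8 that fell. That lean was opposite to the lean over all 138 genes. The integrin gene Itgb7 had an expression change of -1.99 with promoter capture at 1.55, and the lipid transfer gene Mttp had -0.75 with 1.23. Abhd2, Parp12, Unc13c and the cell death gene Bcl2l11 had expression changes of 0.51, 0.55, 0.64 and 0.41 with capture at -0.68, -0.59, -0.72 and -0.77. The other 4, Dusp13, Scn10a, Ccdc155 and Tlk1, had the same sign in both, with expression at -0.50, -0.59, -1.25 and 0.23 and capture at -0.66, -0.60, -0.60 and 1.85. Expression values are those in the authors' deposited table divided by 2, and the capture values are from the deposited promoter table. With RRBS, 200 of the irradiation genes had a listed radiation region within 2 kb of the start. Group 1 was the higher side for 46% of the genes that rose and for 51.7% of those that fell (Fisher exact p = 0.476), so no relation was detected.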

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

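In the stromal vascular fraction the authors' deposited interaction table listed 1207 regions, and in satellite cells it listed 1057, places where the authors' own test of the difference found that the effect of radiation varied with diet. Of these regions 42.8% and 49.2% differed by less than 1 percentage point. Both tables give unadjusted p-values, and how many of these regions an adjustment would keep could not be tested.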

How the results depend on the processing

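Thresholds of 0.1 for adjusted p and of 0.0001 for unadjusted or median p were chosen after the data were seen. Of 81 alternatives to the main results 54 kept their side of the threshold and stayed within 1.5 times the main count, and 27 did not. For irradiation over both diets the 827 genes became 272 at an adjusted p under 0.01, 91 under 0.001, 1695 under 0.1, 118 with an absolute log2 fold change of at least 1 and 400 at or above the median abundance. On chow the 155 became 24, 9, 322, 73 and 72 in that order, and on the high fat diet the 8 became 18 under 0.1 and 5 at or above the median abundance. Lists passing the test of direction went from 0 to 1 under 0.1, and genes shared by the diets from 5 to 13. With an absolute log2 fold change of at least 1, MBD regions fell to 113 promoters, 66 shores and 474 exons, and at an unadjusted p under 0.0001 to 70 promoters, 10 islands, 39 shores and 81 exons. At least 10 points of difference left 1684 radiation, 4832 diet and 497 interaction regions in the stromal vascular fraction and 5101, 4606 and 347 in satellite cells. These counts fall or rise because fewer or more genes and regions pass.

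Of 50 alternatives for the splits of directions that departed from even, 43 kept it, 5 no longer departed from even and 2 reversed. Reversed were MBD promoters, from 24.1% to 75.2% higher, and shores, from 34.2% to 90.9%, at an absolute log2 fold change of at least 1. The higher regions had median log2 fold changes of 1.48 for promoters and 1.54 for shores, and the lower regions -0.70 and -0.75. That minimum therefore kept most of the higher regions and removed most of the lower ones. Why higher and lower regions differed in size was not tested. Lost were irradiation over both diets at 55.9% with that minimum and 48.6% under 0.1, the diet splits at 50.9% in the stromal vascular fraction and 49.5% in satellite cells with 10 points, and radiation in satellite cells at 49.3% with a median p under 0.0001. No gene was left on the high fat diet or for diet in irradiated mice under 0.01 and 0.001, and the diets could not be compared under 0.01 or at or above the median abundance. No paired analysis was possible because the tables hold the authors' comparisons and no values of single samples. For the same reason leaving out replicates, other normalizations, filters on counts, coverage minimums and adjusted p-values for MBD and RRBS were not run, and depth per library is unknown.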

Other observations

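The lists of amino acid response genes and of neuronal genes and the test of gene span by abundance were chosen only after the data were seen. Genes that cells induce through the transcription factor ATF4 when amino acids run short were lower after irradiation in satellite cells. Of 49 genes in a list of such genes, 35 fell and 0 rose over both diets at an adjusted p under 0.05 in the authors' deposited table, against 3.28 expected by size. They included amino acid transporters, with mean log2 fold changes of -0.80 for Slc7a5 and -0.72 for Slc3a2, the serine synthesis enzymes Phgdh at -0.43 and Psph at -0.52, the transfer RNA synthetase Gars at -0.45, and the regulators Atf5 at -0.67, Trib3 at -1.68 and Chac1 at -0.76. Stc2 stood at -0.82. Part of the list had been seen among changed genes when it was written, but of the 33 members not seen before, 22 fell and 0 rose (Fisher exact p = 1.77e-06 against the other listed genes), so the pattern does not rest on the members already seen. A lower amino acid stress response in irradiated satellite cells is a hypothesis from these data, and no technical explanation for it was tested. Over both diets the fibroblast list also had 4 lower and 0 higher, and fold change followed gene span (rank correlation 0.293), and neither was separated from the fall of these genes.

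In a list of neuronal genes 16 of 41 rose and 0 fell over both diets, among them Cadps at 2.44, Dcx at 2.31 and Nefl at 1.48 in the authors' deposited table divided by 2. This list rests on members already seen, since of 25 others 1 rose, Ina at 0.89, and 0 fell, against 1.64 expected by size (exact hypergeometric p = 0.817). The Fisher exact p of 0.446 for direction comes from 1 gene and decides nothing, so these data do not show that neuronal genes moved as a group.

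Genes that rose were longer in the genome than genes that fell, with median spans of 53.5 and 16.5 kb and a rank correlation of fold change with span of 0.293 across the 827 genes, which are not independent replicates (permutation p = 1e-05, the smallest that 100000 permutations can give). Abundance as the whole cause is argued against, because the correlation was 0.188 or more in each of 4 equal classes of abundance. Without the 16 listed members of the neuronal list the correlation was 0.279. So few of the 827 genes could hardly have changed it, so this decides nothing about them. Differences in RNA quality or in unspliced RNA between groups stay open as candidate explanations and were not tested.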
